A study of Mus musculus with 6 samples.

How the data were processed

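The samples were adipose progenitors of adult AdipoTrak mice, in which the Pparg promoter drives a tetracycline transactivator that switches on a green fluorescent histone (H2B-GFP). Per the labels, the mice were 2 to 6 months old and ate plain chow or chow with 0.0075% rosiglitazone, a PPARgamma agonist of the thiazolidinedione class, for 2 months. Inguinal, interscapular and gonadal white fat was treated with collagenase (2 hours, 37 degrees C), and flow cytometry collected the stromal-vascular cells that carried GFP. Per the series' design text, each group had 3 cohorts of 3 to 4 mice, so an array stands for a pool of animals. Total RNA was labelled as biotinylated cRNA and hybridised to Illumina mouse bead arrays with 45281 probes.

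The deposited non-normalized table gives the intensity of every probe on each of the 6 arrays, on a linear scale and, from its values, with no background subtracted. Beside each intensity the authors deposited a detection p-value. A second deposited table holds intensity values normalized between arrays; its method was not given in the sources used here, but its columns share a distribution, with sorted columns no more than 0.446 units apart. The deposited series table equals that normalized table, with a largest difference of 0. In 45 cells the detection p-value differed between the deposited tables, by at most 0.00107. The scanner software was not given in the sources used here. No deposited per-sample column was left unused.

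Total intensity per array ranged from 9478692 to 14831319 units and detected probes from 15492 to 17379. For arrays, the number of arrays limits the precision.

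Starting from the non-normalized table, background was corrected with the normexp model, estimated from the detection p-values, with an offset of 16, followed by quantile normalization and log2 (limma 3.58.1 in R 4.3.3). Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept, which left 16442 probes. Rosiglitazone was compared with untreated by lmFit and eBayes in limma with no covariates, and p-values were adjusted by the Benjamini-Hochberg method over all kept probes, with a threshold of 0.05. Fold changes are on the normalized log2 scale with the offset, which understates the change of dim probes. A probe with no detection on any array of a group has only a bound there; the bright group's mean was then set against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own value.

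Gene names came from the platform annotation supplied with the data. Of the 45281 probes, 34885 had 1 symbol, 18 had several and 10378 were unnamed here. Matching by Entrez number to a RefSeq gene table found 34807 of the named probes and changed 0 symbols. A gene was represented by its brightest kept probe, which gave 9760 genes. Of 94 changed genes with several kept probes, 39 had every kept probe past the threshold, 0 had probes past it in both directions and 4 had a probe with the opposite sign that did not pass. No coordinates are printed because the tables name no genome build.

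A total of 46 gene lists, 10 of them markers of other cell types or of sex, were fixed before the data were examined, as were the tests, the other settings to be tried and the rule for naming genes. Lists with at least 5 kept members, 43 in all, were tested with camera in limma with a preset inter-gene correlation of 0.01, and p-values were adjusted over these lists. Named genes were the 12 largest rises and 12 largest falls past the threshold with no overlap between groups, the members with the smallest p-values in each list that passed and in 8 lists of prior interest, Pparg, Fabp4, Adipoq, Cd36 and Pdk4, and the 3 brightest members of a marker list that passed. Genes with clone or predicted names were counted but not named.

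The same code was tested on simulated data with 16442 probes, of which 200 were changed in each of 5 draws. For this comparison it recovered 0.1% of probes changed 1.5-fold, 37.6% of those changed 2-fold and 90.9% of those changed 4-fold, with 0, 2.8 and 7.8 false calls per draw. Alternatives covered the background correction, normalization, source table, probe filter, variance model, array weights, the replicate number as a block, each array left out, thresholds, averaging of probes and other list tests. A block for the bead chip was not run, since the column names and labels identify no chip.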

Results

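Gene expression was measured in GFP-positive stromal-vascular cells, a fraction the study describes as adipose progenitors, sorted from the white fat of adult AdipoTrak mice. The 6 arrays comprised 3 cohorts on plain chow and 3 cohorts fed 0.0075% rosiglitazone, an agonist of the nuclear receptor PPARgamma, for 2 months. Each cohort pooled 3 to 4 mice, so the spread between arrays is that between pools. Total intensity was 14510640, 9478692 and 14831319 units on the untreated arrays and 10330923, 13615604 and 11663031 units on the rosiglitazone arrays, and 34.2% to 38.4% of the 45281 probes were detected per array. Pearson correlations over kept probes were 0.971 to 0.985 between arrays of a group and 0.958 to 0.974 between arrays of different groups, and no array was a duplicate of another.

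The comparison of rosiglitazone with untreated cells asks which transcripts change in adipose progenitors under a PPARgamma agonist. Most changed probes were lower with rosiglitazone, and markers of macrophages and inflammatory genes were among them. Genes of fatty acid and cholesterol synthesis were among those that rose. Of the 16442 probes kept, 392 passed an adjusted p of 0.05, 81 higher and 311 lower with rosiglitazone, which corresponded to 61 and 234 named genes. All 392 had no overlap between the groups; over all kept probes this was so for 17.2%, where chance gives 10%. The smallest change called was 1.66-fold. Untreated replicate 1 weighed most on the count, which was 216 probes without it. The number of higher probes was 31 without untreated replicate 1, 42 without untreated replicate 2 and 39 without rosiglitazone replicate 2, and 30 with median scaling in place of quantile normalization. Of 47 named genes past the threshold, 23 lost their call without a detection filter, and 27 had a log2 change smaller by over 1.5 times on the authors' normalized table, 32 without background correction.

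**Figure D1:**
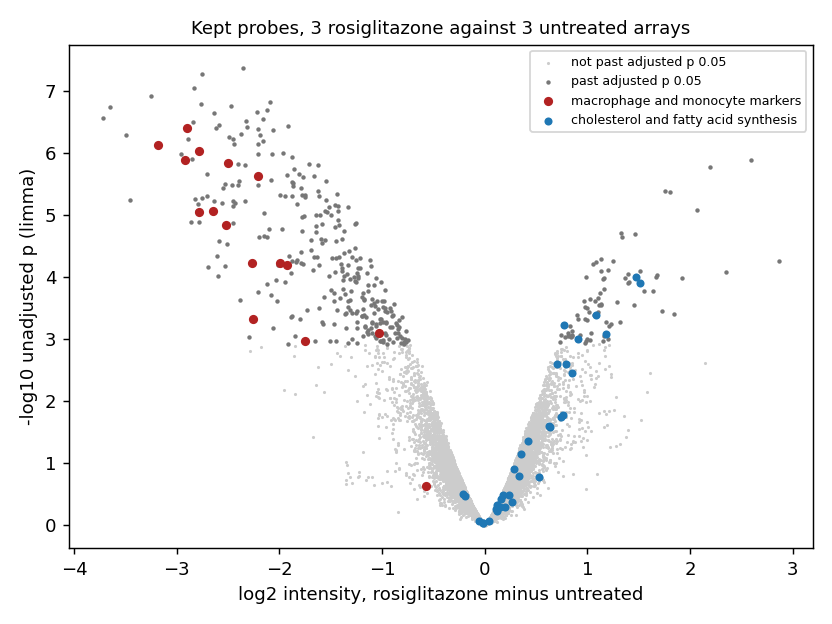
Each point is a kept probe, with the log2 difference in intensity (rosiglitazone minus untreated, 3 arrays each) on the x axis and −log10 of the unadjusted limma p on the y axis. Darker grey marks the 392 probes past an adjusted p of 0.05, red the 16 macrophage and monocyte markers, all on the left, and blue the members of the cholesterol and fatty acid synthesis lists.

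Macrophage and monocyte markers fell together. Of 16 measured members of this list, 15 fell, and the same 15 counted when p was adjusted over the list alone; the median log2 change was -2.38 (camera adjusted p = 4.32e-28, and adjusted p = 0.267 with an estimated correlation). C1qb, a subunit of the complement initiator C1q, went from 10.81 ± 0.23 to 7.62 ± 0.67 log2 units (SD, n = 3), 9.10-fold lower (adjusted p = 0.00037). Among the brightest members, the lysosomal protein gene Laptm5 was 3.79-fold lower and the lysozyme gene Lyz2 3.97-fold lower, with adjusted p = 0.0062 and 0.0060. Lyz1 was 2.04-fold lower by its brightest probe (adjusted p = 0.038), while its 2 other kept probes had log2 changes of -1.92 and -1.84 (adjusted p = 0.0499 and 0.052), and probes for these closely related lysozyme genes can share signal; its call was lost with median scaling and without each array in turn except rosiglitazone replicate 2. The remaining member, the haemoglobin scavenger receptor gene Cd163, had a log2 change of -0.57 (adjusted p = 0.70). The mean of the list was 9.75, 9.21 and 9.67 on the untreated arrays and 7.54, 7.68 and 6.62 on the rosiglitazone arrays. The 3 measured erythroid markers, too few for a list test, had a median log2 change of -1.03 with 0 past the threshold, 1 lower when adjusted over the list alone; their mean was 7.50, 8.64 and 6.32 on the untreated arrays and 6.77, 6.46 and 6.57 on the rosiglitazone arrays.

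Further genes were among the 12 largest falls, some of them members of the fixed lists and others of none. Trem2, a lipid-sensing receptor of myeloid cells, fell from 9.48 ± 0.30 to 5.76 ± 0.69 log2 units (SD, n = 3), 13.2-fold (adjusted p = 0.00031). The non-classical MHC gene H2-M2 was 12.5-fold lower, the growth factor gene Gdf3 11.3-fold lower and the macrophage elastase gene Mmp12 10.9-fold lower, with adjusted p = 0.00031, 0.00034 and 0.0011. Ms4a7, Dpep2, Lat2 and Nckap1l were 9.51-fold, 7.78-fold, 7.42-fold and 7.20-fold lower. The beta-glucan receptor gene Clec7a, one of the macrophage markers counted above, and the haptoglobin gene Hp were 7.46-fold and 7.25-fold lower. H2-M2, Gdf3 and Clec7a were each detected on 2 of 3 rosiglitazone arrays, so their folds rest partly on signal at background. For Dpep2 and Clec7a another kept probe was not detected on any rosiglitazone array and did not pass (adjusted p = 0.055 and 0.052). Macrophage markers had a median log2 change of -2.38 over these arrays, and whether the genes named here fell in the progenitors was not tested.

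Inflammatory genes also fell. Among 25 measured cytokines and chemokines, 7 fell, 0 rose and 18 did not pass; 9 fell when adjusted over the list alone, and the median log2 change was -0.57 (camera adjusted p = 3.5e-09, and adjusted p = 0.41 with an estimated correlation). That median was -0.31 without untreated replicate 1 and -0.35 without rosiglitazone replicate 3. The chemokine Ccl3 was 5.49-fold lower, the iron-binding protein gene Lcn2 4.61-fold lower, Il1b 3.85-fold lower and Tnf 3.45-fold lower, with adjusted p = 0.00085, 0.00086, 0.0010 and 0.0060, and Lcn2 was detected on 2 of 3 rosiglitazone arrays. In the complement list 4 of 14 members fell, 4 also when adjusted over the list alone, with a median of -0.45 (camera adjusted p = 3.29e-05, and adjusted p = 0.18 with an estimated correlation). These were C1qa, C1qb, C1qc and the alternative pathway gene Cfb, and the first 3 are also macrophage markers; without such shared members, an alternative added after seeing the data, the list no longer passed (adjusted p = 0.078). The macrophage marker list fell by 2.38 on the log2 scale in the same arrays.

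Among matrix remodelling enzymes and inhibitors 3 of 20 members fell, 5 when adjusted over the list alone, with a median log2 change of -0.32 (camera adjusted p = 8.47e-05, and adjusted p = 0.18 with an estimated correlation), which was -0.16 without rosiglitazone replicate 1, -0.20 without untreated replicate 3 and -0.16 on the authors' normalized table. The collagenase gene Mmp13 was 4.67-fold lower and the gelatinase gene Mmp9 3.10-fold lower, beside Mmp12, with adjusted p = 0.00031 and 0.0053, while Timp1 had a log2 change of -1.33 that did not pass (adjusted p = 0.096). Structural extracellular matrix genes did not shift as a list: the median was -0.02 over 38 members (camera adjusted p = 0.91), of which 1 fell, Col8a1, 3.45-fold lower (adjusted p = 0.00091). Adjusted over the list alone, 1 was higher and 1 lower; the higher one was Col18a1, with a log2 change of 0.71 (adjusted p = 0.076 over all kept probes). Mmp13 and Col8a1 were each detected on 1 of 3 rosiglitazone arrays, where their means, 4.65 and 4.55 log2 units, lay below the lowest detected signals of 4.68 to 4.76, so their folds are set against background. Mural cell genes, which mark pericytes and smooth muscle, had a median of -0.45 (camera adjusted p = 0.0012, and adjusted p = 0.29 with an estimated correlation), which was -0.17 without untreated replicate 3, -0.30 without rosiglitazone replicate 1 and -0.29 on the authors' normalized table. Of 11 members 2 fell, 3 when adjusted over the list alone; the receptor gene Notch3 was 2.27-fold lower and the adhesion molecule gene Mcam 1.90-fold lower, with adjusted p = 0.041 and 0.019, and another kept Mcam probe had a log2 change of -0.61 that did not pass (adjusted p = 0.145). These calls and that of Cfb were lost with median scaling and without untreated replicate 1, and each was also lost without at least 1 other array; those of Notch3 and Cfb were lost on the authors' normalized table and without background correction or a filter as well. Macrophage markers fell in the same arrays, with a median of -2.38. The endothelial markers did not pass (0 of 15, 0 adjusted over the list alone, median -0.22, camera adjusted p = 0.14); their mean was 8.59 on rosiglitazone replicate 3 against 7.59 and 7.64 on the other rosiglitazone arrays.

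**Figure D2:**
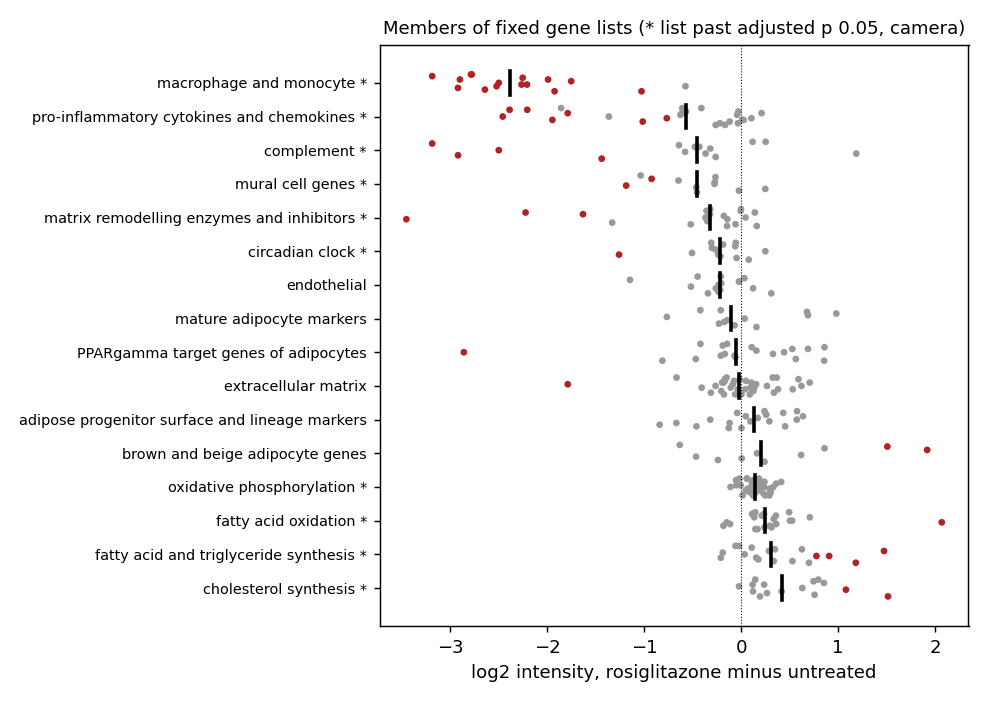
Points are genes of 16 of the gene lists, with the log2 difference in intensity (rosiglitazone minus untreated) on the x axis and a list per row; red points passed an adjusted p of 0.05 over all kept probes, black bars are medians and an asterisk marks lists past the camera test. The macrophage and monocyte list has its median at -2.38, and the cholesterol synthesis list at 0.42.

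Genes of lipid synthesis rose. In the fatty acid and triglyceride synthesis list 4 of 18 members rose, 5 when adjusted over the list alone, and the median log2 change was 0.31 (camera adjusted p = 0.00070, and adjusted p = 0.20 with an estimated correlation), which was 0.21 without untreated replicate 2 and 0.17 on the authors' normalized table. The desaturase gene Scd1 was 2.78-fold higher, from 9.91 ± 0.26 to 11.39 ± 0.43 log2 units (SD, n = 3; adjusted p = 0.0083). Scd2 and Fads1, also desaturases, were 2.27-fold and 1.71-fold higher, and the elongase gene Elovl6 1.88-fold higher, with adjusted p = 0.039, 0.030 and 0.044, and Scd2 was detected on 2 of 3 untreated arrays. Cholesterol synthesis genes had a median of 0.42 (camera adjusted p = 8.32e-05, and adjusted p = 0.41 with an estimated correlation); 2 of 15 members rose, 6 when adjusted over the list alone, and the median was 0.24 on the authors' normalized table. Fdps, which makes farnesyl diphosphate, was 2.86-fold higher and the squalene epoxidase gene Sqle 2.12-fold higher, with adjusted p = 0.0096 and 0.023. Srebf1, which encodes a transcription factor of lipid synthesis, was 1.96-fold higher (adjusted p = 0.016). Calls for Sqle, Scd2, Elovl6, Fads1 and Srebf1 were lost with median scaling, and without untreated replicate 1 as well as without at least 1 other array. Those of Scd2, Elovl6 and Srebf1 were also lost on the authors' normalized table and without background correction, that of Scd2 with an offset of 50, and those of Scd1, Fdps, Sqle, Scd2 and Elovl6 without a filter. Over the same arrays the macrophage markers fell and the progenitor markers had a median of 0.13 that did not pass. The 4 measured mesothelial markers, too few for a list test, had a median of 0.44, with 4 positive changes and 0 past the threshold, 0 also when adjusted over the list alone.

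Fatty acid oxidation genes had a median log2 change of 0.24 (camera adjusted p = 0.00070, and adjusted p = 0.29 with an estimated correlation), and 1 of 21 members rose, 2 when adjusted over the list alone. That gene, the peroxisomal thiolase Acaa1b, was 4.20-fold higher (adjusted p = 0.0014), and was detected on 2 of 3 untreated and all 3 rosiglitazone arrays. Acaa2, Cpt2 and Etfb had log2 changes of 0.71, 0.53 and 0.50 that did not pass. Oxidative phosphorylation genes had a median of 0.15 with 37 of 42 changes positive and 0 past the threshold, 0 also when adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.61 with an estimated correlation); the median was 0.22 without untreated replicate 1. Circadian clock genes had a median of -0.21 (camera adjusted p = 0.033, and adjusted p = 0.29 with an estimated correlation); the median was -0.11 on the authors' normalized table. Of 13 members 1 fell, 1 also when adjusted over the list alone: Ciart, a repressor of the clock, 2.39-fold lower (adjusted p = 0.0040). Of its 2 other kept probes 1 passed (log2 change -1.37, adjusted p = 0.014), and the other was not detected on any rosiglitazone array and did not pass (adjusted p = 0.41). For both of these lists the call was lost with median scaling (adjusted p = 0.22 and 0.11). It was also lost for oxidative phosphorylation without untreated replicates 2 or 3 or rosiglitazone replicate 2 (adjusted p = 0.13, 0.10 and 0.095), and for the clock without untreated replicate 3 or rosiglitazone replicate 1 (adjusted p = 0.13 and 0.17) or with array weights (adjusted p = 0.087). In the same arrays the macrophage markers fell, with a median of -2.38, and the mesothelial markers had a median of 0.44, with 0 past the threshold.

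The remaining largest rises came from varied genes. The ribonuclease gene Rnase2a was 7.28-fold higher (adjusted p = 0.0057), and its probe can share signal with close paralogs of the same family. Its call was lost without a filter and with a trended, robust variance (adjusted p = 0.13 and 0.096). The mitochondrial subunit gene Cox8b, abundant in brown fat, was 3.78-fold higher, and Cited1, a marker of beige adipocytes, 2.85-fold higher, with adjusted p = 0.0083 and 0.0073, and Cited1 was detected on 2 of 3 untreated arrays. These were the 2 members of 10 measured brown and beige genes that rose; 2 also counted when adjusted over the list alone, and the list did not pass (median 0.20, camera adjusted p = 0.27). Of its changes 7 were positive and 3 negative. Cox7a1 and Ppargc1b had log2 changes of -0.46 and -0.63 that did not pass (adjusted p = 0.26 and 0.39). Of 8 measured skeletal muscle markers 0 passed, with 1 higher when adjusted over the list alone (median 0.17, camera adjusted p = 0.39). The sulfotransferase gene Chst8 was 3.60-fold higher and Slitrk1, a neuronal membrane protein gene, 3.49-fold higher, with adjusted p = 0.022 and 0.0010; the other kept Slitrk1 probe, detected on 1 of 3 untreated and 2 of 3 rosiglitazone arrays, did not pass (log2 change -0.09, adjusted p = 0.90). Rbp7 and Crabp1, which encode retinoid-binding proteins, were 3.31-fold and 2.94-fold higher, and Prxl2a and Lrrc15 3.20-fold and 3.17-fold higher. Chst13 and the connexin gene Gjb6 were not detected on any untreated array and were at least 2.71-fold and 2.80-fold higher, with adjusted p = 0.00098 and 0.012. The calls of Chst8, Crabp1, Rbp7 and Gjb6 were lost without untreated replicate 1, and each was also lost without at least 1 other array, without background correction and without a filter. Those of Chst8 and Gjb6 were lost on the authors' normalized table too, and that of Rbp7 with a trended, robust variance. Cox8b, Cited1, Prxl2a and Lrrc15 lost theirs without a filter. In the same arrays the macrophage markers fell, with a median of -2.38. The mean of the mesothelial markers was 6.60, 6.25 and 6.16 on the untreated arrays and 7.46, 7.12 and 6.01 on the rosiglitazone arrays, and of these markers Upk3b had a log2 change of 1.21 (adjusted p = 0.24).

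**Figure D3:**
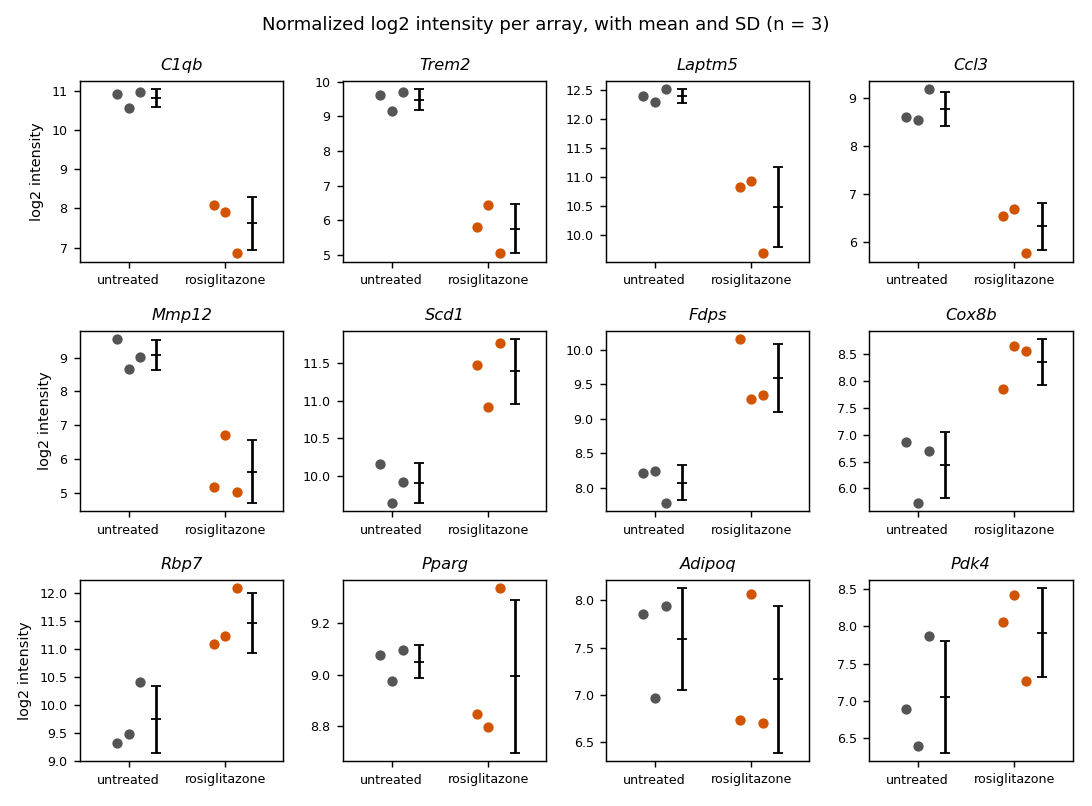
Normalized log2 intensity (y axis) of 12 genes on each of the 3 untreated and 3 rosiglitazone arrays; points are arrays, and bars are the mean and SD. C1qb, Trem2, Laptm5, Ccl3 and Mmp12 lie lower on every rosiglitazone array, Scd1, Fdps, Cox8b and Rbp7 higher, and the groups overlap for Pparg, Adipoq and Pdk4.

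Adipocyte target genes of PPARgamma did not shift as a list. Over 19 measured members, of 32 in the list, the median log2 change was -0.06 (camera adjusted p = 0.86), and 1 fell, 2 when adjusted over the list alone; the member that fell was Hp. Hilpda, Cidec and Aqp7 had log2 changes of -0.81, 0.69 and 0.86 that did not pass (adjusted p = 0.092, 0.23 and 0.38). Cidec was detected on 1 of 3 untreated arrays. The other kept Aqp7 probes had log2 changes of 1.11 and 1.00 (adjusted p = 0.081 and 0.29). Pparg itself was 9.05 ± 0.06 in untreated and 8.99 ± 0.30 log2 units in rosiglitazone cells (SD, n = 3, adjusted p = 0.95). Cells of both groups were sorted on a reporter driven by the Pparg promoter, so this does not show whether rosiglitazone changes Pparg outside the sorted cells. Adipoq and Pdk4 had log2 changes of -0.42 and 0.86 (adjusted p = 0.74 and 0.40), which ranged from -0.87 to -0.19 and from 0.53 to 1.27 when each array was left out in turn; neither passed in any of these fits. The Fabp4 probe was detected on 0 arrays and the Cd36 probe on 1 of 6, so neither was tested, and a probe without signal does not show that its gene was silent. Among 16 adipogenic transcription factors Srebf1 alone rose, 1 also when adjusted over the list alone (list median 0.03, camera adjusted p = 0.65). The anti-adipogenic regulators had a median of 0.03 (camera adjusted p = 0.71) and 0 of 18 passed, with 1 higher and 1 lower when adjusted over the list alone; Sox9 and Gli2 had log2 changes of -0.76 and 0.70 (adjusted p = 0.099 and 0.11), while a second, dimmer Sox9 probe had a log2 change of -0.90 that passed (adjusted p = 0.023). Progenitor markers (0 of 20 past the threshold, 0 adjusted over the list alone, camera adjusted p = 0.45) and cell cycle genes (0 of 27, 0 adjusted over the list alone, median -0.04, camera adjusted p = 0.87) did not pass. Mature adipocyte markers had a median of -0.11 (0 of 12, 0 adjusted over the list alone, camera adjusted p = 0.91).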

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

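The alternatives were planned before the data were examined, except the removal of shared macrophage members from other lists, which was added afterwards. The 392 changed probes (81 higher, 311 lower) became 260 (30 higher) with median scaling, 157 (26 higher, 131 lower) without a detection filter and 248 (191 lower) with a stricter filter, which tested 11114 probes. Higher probes numbered 168 with array weights and 148 at an adjusted p of 0.10. A looser threshold adds calls by definition. Changing the filter left the log2 change of each probe as it was and altered only the variance shared across probes and the number of probes adjusted over. The cause of the other moves was not tested. Leaving out each array gave 216 to 435 changed probes, 31 to 116 higher and 185 to 319 lower, on fewer samples. The number of shifted lists, 10 (4 higher, 6 lower), was 0 with an estimated correlation (0 higher, 0 lower; lowest adjusted p = 0.18, 7 lists at an unadjusted p under 0.05) and 6 with fry (3 lower), which tests whether a list moves on balance one way; these were 5 of the 10 and the retinoid list. The calls of cholesterol synthesis, mural cells, cytokines and the clock (adjusted p = 0.085 each) and of oxidative phosphorylation (adjusted p = 0.15) were lost with fry. Every other alternative gave 9 to 13 lists. Pparg, which did not pass, moved between -0.2264 and 0.0414 on the log2 scale when arrays were left out. Of 47 named genes past the threshold, 3 of 19 higher and 18 of 28 lower ones kept their call under all 16 alternatives run on them, and 9 and 24 did when the absence of a filter was set aside; the stricter filter tested 33 of the 47. The 23 calls lost without a filter were, beside those named with the lipid genes and the largest rises, those of Mmp9, Mmp12, Hp, Tnf, Laptm5, Lyz1, Lyz2, Cfb and Notch3. Median log2 changes that moved by over 1.5 times without background correction were 0.15 for fatty acid synthesis, 0.23 for cholesterol synthesis, -0.26 for mural cells, -0.16 for matrix remodelling and -0.09 for the clock. Without a filter they were 0.17 for fatty acid synthesis, -0.27 for mural cells, -0.34 for cytokines and -0.11 for the clock. An offset of 50 gave 0.25 for cholesterol synthesis and -0.19 for matrix remodelling, a stricter filter 0.27 and -0.16, array weights -0.12 for the clock and median scaling 0.0879 for oxidative phosphorylation. No direction of a called gene or list reversed.

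With the replicate number as a block, 475 probes and 10 lists passed. Same-numbered arrays deviated from their group means with correlations of 0.05, -0.01 and 0.35, and only the arrays numbered 3 correlated best with their own number. Untreated replicate 1 correlated best with rosiglitazone replicate 2 (0.15), and untreated replicate 2 with rosiglitazone replicate 1 (0.27). Each array numbered 3 correlated negatively with the other group's arrays numbered 1 and 2 (-0.12 to -0.30). Deviations cancel within a group, so this follows largely from the positive correlation between the arrays numbered 3. Numbers 1 and 2 thus gave no sign of pairing the samples. The second principal component, with 25.8% of the variance between arrays, set the arrays numbered 3 apart. Their scores were 27.5 (untreated) and 24.6 (rosiglitazone), against -29.3 to 0.46 on the other arrays. Whether the arrays numbered 3 shared a batch was not tested. A chip block was not run. Signal over background limits dim genes: 16442 of 45281 probes could be tested, and simulated 1.5-fold changes were recovered in 0.1% of probes.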

Other observations

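The genes and tests in this part were chosen after the values were seen, except the gene lists themselves and the tests of other splits and of the cytokine, complement and matrix lists, whose outcomes had not been seen. Among single genes picked in this way, H2-Ab1 and H2-Eb1, which encode MHC class II chains, went from 13.26 ± 0.16 to 10.81 ± 0.65 and from 12.85 ± 0.15 to 10.06 ± 0.80 log2 units (SD, n = 3), 5.46-fold and 6.91-fold lower. The invariant chain gene Cd74 was 5.47-fold lower and the peptide-loading gene H2-DMa 4.34-fold lower. Adjusted p for these genes was 0.0011, 0.0012, 0.0013 and 0.0029. The class II transactivator gene Ciita was detected on 3 untreated and 0 rosiglitazone arrays. The macrophage markers fell in the same arrays, with a median log2 change of -2.38.

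In the list of retinoid metabolism and signalling 1 of 15 members rose, Crabp1, and 4 when p was adjusted over the list alone; the list did not pass camera (median log2 change 0.14, adjusted p = 0.14), which sets it against other genes, but passed fry, which asks whether its members move on balance one way (adjusted p = 0.012). Rarres1, Stra6 and Rbp4 had log2 changes of 1.08, 0.98 and 0.68 that did not pass over all kept probes (adjusted p = 0.099, 0.10 and 0.13), and Stra6 was detected on 1 of 3 untreated arrays. Of 5 measured Schwann cell and nerve markers 0 passed, with 1 higher when adjusted over the list alone (median -0.08, camera adjusted p = 0.91).

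The fall of macrophage markers, with a median log2 change of -2.38, was weighed against array brightness and normalization. Of 10000 random lists matched on mean intensity, the lowest median was -0.30, and with median scaling the list's median was -2.41, so neither accounts for it. A lower share of macrophages among the sorted cells is a candidate explanation: members deviated together within groups, with a mean pairwise correlation of 0.74 against a 95th percentile of 0.10 in random lists, as a coordinated change within the same cells also could. Sorting on GFP would remove macrophages that lack the reporter, and whether those present carried it, passed the gate without it or were fewer in the tissue under rosiglitazone was not tested. Other splits of the 6 arrays called at most 1 probe against 392 for the treatment split, which 1 of 10 splits reached. They called 2 to 9 lists against 10, again reached by 1 of 10. Every split that mixed the treatments thus also had lists past camera at the preset correlation. A list call does not by itself single out the treatment. With 10 splits the share cannot be under 0.1.

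For the other inflammatory lists, the same candidate explanation was tested by how closely members followed the macrophage mean within groups, with macrophage list members left out. The cytokine and chemokine list lay at percentile 100 of random lists, which is consistent with a lower share of macrophages for this list. The complement list lay at percentile 26.7, below the middle of random lists, the bound set in advance against the explanation, but within their spread, which decides nothing; that the spread had to be exceeded was applied after the value was seen. The matrix remodelling list lay at percentile 3.90, which goes against that explanation for the list's typical member but does not decide it. Random lists were drawn gene by gene and lack the correlation among a list's members, so percentiles this far out may be too extreme. Within the rosiglitazone group the macrophage mean also varied mostly through replicate 3, at 6.62 against 7.54 and 7.68. The test takes a median over members, so it does not speak to the 3 that passed, Mmp9, Mmp12 and Mmp13. The list's mean log2 change, -0.57 against a median of -0.32, rests partly on these. An effect of rosiglitazone on these genes in the progenitors themselves stays open.

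The rise of lipid and mitochondrial lists could be a relative gain from having less macrophage RNA. Each list's mean minus that of the progenitor markers was compared between arrays. The lowest rosiglitazone array exceeded the highest untreated one by 0.20 for cholesterol synthesis, 0.18 for fatty acid and triglyceride synthesis and 0.0907 for fatty acid oxidation. For oxidative phosphorylation the groups overlapped, at -0.0803. A relative gain would raise progenitor markers as well, but their median log2 change was 0.13, and that of extracellular matrix genes was -0.02. Where there was an excess, it argues against a relative gain as the whole account of that list's rise. The lists were taken up because they rose against other genes in these arrays, and the progenitor markers had not shifted. The size of the excess may thus be overstated. For oxidative phosphorylation a relative gain stays open. Admixture of mature adipocytes would raise their markers as much. The median log2 change of those markers was -0.11, below the median of each of the 4 lists, with 5 of 12 changes positive. Their upper quartile was 0.29. The list median minus that quartile was 0.13 for cholesterol synthesis, 0.0239 for fatty acid synthesis, -0.0469 for fatty acid oxidation and -0.1431 for oxidative phosphorylation. Without untreated replicate 3 or rosiglitazone replicate 1 it was -0.0270 and -0.0602 for cholesterol synthesis and -0.0338 and -0.0679 for fatty acid synthesis, where it was also below 0, at -0.0248, without untreated replicate 2, and admixture stays open for all 4 lists, as does a response of the progenitors to rosiglitazone; that the excess had to hold with each array left out was required after the values were seen, and the bound first set would have argued against admixture for the cholesterol and fatty acid synthesis lists.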
